A study of Mus musculus with 8 samples.

How the data were processed

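Liver RNA of mice given ConA was profiled at 8 h in 2 groups of 4 libraries, P2X4R-deficient and wild type. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected, cDNA was made with random primers and libraries were sequenced on an Illumina NovaSeq. Sample groups were taken from the genotype given in the labels, and libraries are named here by group and by the number at the end of their titles.

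Per the file headers, the deposited table gives a raw read count and an FPKM value for each gene and library, with gene identifiers, coordinates and a gene length. FPKM, computed by the authors, is the read count scaled to gene length and to the total of the library. Recomputing it from the counts and lengths gave values within 7e-05% of those listed. The submitters' processing notes name cutadapt, a read trimmer, and HISAT2 2.0.5, a spliced aligner. The counting program, its use of strand, the annotation release and the genome build are not given in the sources used here. Coordinates are therefore printed as the table lists them. Starts equalled those of the GENCODE M21 annotation of GRCm38 for 2.3% of the shared identifiers, so GRCm38 coordinates were not used. Without stated strand, reads of overlapping and antisense genes cannot be separated, and genes with near-identical copies, such as the major urinary protein (Mup) family, have uncertain counts.

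The table holds 21899 genes, of which 5754 had 0 reads in every library. Library totals ran from 15445285 to 16604190 reads. A floor of 3 reads, the upper limit that a count of 0 allows, corresponds to 0.181 to 0.194 CPM (counts scaled to a common library total). Intervals and floors on counts cover counting error only, since reads were amplified and carry no molecular identifiers. Replicate libraries differed by more than counting noise, with a chi-square per degree of freedom of 21.53 to 109.42 over genes with 20 or more reads in the pair. That excludes repeated sequencing of the same library, and does not show whether libraries came from separate animals.

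The design fixed before the data were examined called for edgeR's quasi-likelihood test if read counts were present, and for limma on log2(FPKM + 1) otherwise. Counts were present, so edgeR 4.0.16 (R 4.3.3) was used on the deposited counts with TMM scaling, its default expression filter, no covariate and no robust option. The filter left 11380 genes and removed 10519. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and adjusted p-values below come from this test unless another is named. The standard error of a log2 fold change was its size divided by the square root of the quasi-likelihood F statistic. CPM values are TMM-scaled and given as mean ± SD over 4 libraries.

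The genes named were set by a rule written before the data were examined. It takes P2rx4 first, then the 12 largest rises and the 12 largest falls among genes past the threshold with a mean FPKM of 1 or more in a group and no overlap between the groups. It then takes up to 4 members with the smallest p of each of 36 gene lists fixed in advance for this tissue and treatment, and a few genes that describe a level. Where a further gene is named, it was chosen after its values were seen. A symbol shared by several identifiers, which was so for 20 symbols, stood for the identifier with most reads. List members without a match in the table were not analysed here.

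The 33 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, each adjusted over the lists. In fry, the directional p tests whether a list's genes moved on balance one way and the mixed p whether they changed in either direction. Neither compares a list with other genes. Comparisons of a value over the 8 libraries used exact two-sided permutation tests over the 70 assignments of libraries to groups, for which the smallest possible p is 0.0286. The genome-wide test was also repeated over all 35 splits of the libraries into 4 and 4.

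Counts were simulated for the same 11380 genes, with changes in 200 genes and in the members of 5 gene lists. Among the 200, the edgeR test recovered 49% of the 2-fold and 92% of the 4-fold changes. It gave the right sign for 100% of those called and made 11 false calls. Camera found 5 of 5 lists with simulated changes and called 0 of 30 without. Genes were simulated independently of each other, whereas the estimated correlation was 0.55 in the NF-kB list. These list counts therefore do not show how often camera calls lists of correlated genes wrongly.

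Alternatives fixed in advance included the limma test on log2 FPKM with a pseudocount of 1 or 0.1. It covered genes at an FPKM of 0.5 or more in 4 libraries. Others were no expression filter, a filter at 1 CPM in 4 libraries, robust empirical Bayes, DESeq2 1.42.0, the replicate number as a block, and each library left out in turn. DESeq2 size factors, library size alone and limma's voom with quality weights took the place of alternatives planned for FPKM, once read counts were found. Removal of a trend with GC content or with gene length in each library was added after seeing the data. GC content came from GENCODE M21 transcripts matched by identifier (Biostrings 2.70.1), with a value for 99.9% of tested genes. Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.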

Results

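Gene expression was measured by RNA sequencing in 8 mouse liver samples, 4 of them P2X4R-deficient and 4 wild type, 8 h after ConA. P2X4R is the P2X4 receptor, an ATP-gated cation channel encoded by P2rx4. ConA (concanavalin A) is a plant lectin that activates T cells and causes immune-mediated hepatitis in mice. The question addressed was how loss of the receptor alters liver gene expression during this hepatitis. Livers without ConA were not analysed here, so no background level can be set beside these values. The deficient libraries 1 to 4 held 15445285, 15978516, 16061975 and 16604190 counted reads, and the wild-type libraries 15804184, 15514944, 16417918 and 16218817. The labels do not say that each library came from a separate animal, so p-values measure only the spread between these samples. The labels also give no animal sex, batch or day.

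P2rx4 (ENSMUSG00000029470; chromosome 5, 122845607 to 122867801 on the plus strand) was lower in every deficient liver. The deficient libraries 1 to 4 held 286, 401, 467 and 516 P2rx4 reads, and the wild-type libraries 692, 888, 906 and 898. Mean levels were 24.7 ± 5.33 CPM (SD, n = 4) in deficient and 55.9 ± 8.31 CPM (SD, n = 4) in wild-type livers. P2rx4 fell by 1.18 on the log2 scale (SE 0.19, edgeR adjusted p = 0.00481), leaving 44.2% of the wild-type level with a 95% interval of 33.2% to 58.9%. An exact two-sided permutation test gave p = 0.0286, the smallest possible with 4 against 4 libraries. The sample labels call the genotype a knockdown and the series description gives it as P2X4R-/-. Neither says which part of the gene was altered, and a count over the whole gene does not separate its exons.

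**Figure D1:**
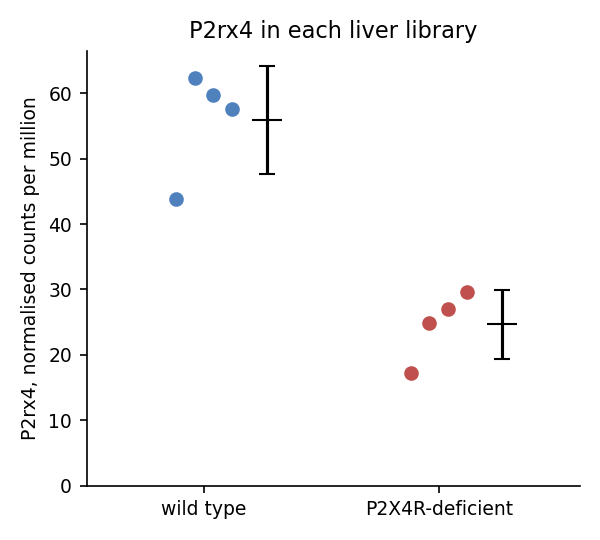
P2rx4 level in normalised CPM on the vertical axis for each of the 8 liver libraries (points) by genotype, with the group mean and SD (bars, n = 4). The deficient libraries lie between 17.3 and 29.6 CPM, all below the wild-type libraries at 43.8 to 62.4 CPM.

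Of 11380 genes tested, 2264 (19.9%) differed between the genotypes at an edgeR adjusted p under 0.05, 1055 higher and 1209 lower in deficient livers. Of these, 460 rose and 569 fell at least 2-fold. Values of the groups did not overlap for 2839 genes (24.9%, against 2.9% by chance), and 1982 of the 2264 genes were among them. The largest rise was in Inhbe (ENSMUSG00000047492), which encodes the inhibin beta E subunit, at 4.03 (SE 0.71) on the log2 scale, from 0.681 ± 0.195 to 11.2 ± 9.74 CPM (SD, n = 4), with deficient libraries between 1.24 and 24.26 CPM. Without deficient 1 it was at 3.31. G0s2 (ENSMUSG00000009633), an inhibitor of triglyceride lipase, rose by 3.97 (SE 0.71), with 128.29 CPM in deficient 1 and 10.19 to 24.07 in the other deficient libraries, and by 2.68 without deficient 1. Slc25a34 (ENSMUSG00000040740), a mitochondrial carrier, rose by 3.33 (SE 0.38). The other largest rises were in Zfp825, Plcd3, Coa4, Dynlt1b, Tubb3, Zfp324, Kctd21, Cdpf1 and Ogg1. In the limma test on FPKM, whose pseudocount of 1 lowers the folds of genes at low FPKM, estimates that moved most but still passed were Slc25a34 at 1.33, Zfp825 at 1.93, Plcd3 at 0.95, Coa4 at 1.05, Tubb3 at 1.01, Kctd21 at 1.09, Cdpf1 at 1.16 and Ogg1 at 0.77.

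The largest fall was in the interferon-inducible gene Ifi208 (ENSMUSG00000066677), with 4 reads in all deficient libraries together and 65 to 147 in each wild-type library. The wild-type level was 104 times the deficient level, with a counting interval of 40.3 to 384. The replication-dependent histone genes H4c17, H1f3, H3c1 and H3c6 were also among the largest falls. H4c17 had 13 reads in deficient and 248 in wild-type libraries, a ratio of 21.1 with a counting interval of 12.1 to 40.3. Sele (ENSMUSG00000026582), which encodes the endothelial adhesion molecule E-selectin, fell by 2.81 on the log2 scale (SE 0.43), from 28.6 ± 16.9 to 4.08 ± 2.24 CPM (SD, n = 4). Phlda1, Lrfn4, Mup2, Mup15, Mup16 and Mup17 completed the set, the Mup genes with uncertain counts because their copies are nearly identical. Another 24 predicted, clone-named or pseudogene entries rose and 13 fell.

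Some of these falls rested on single libraries, and others lost their call with fewer of them. Wild type 3 held 830 Mup15 and 1312 Mup17 reads, and the other wild-type libraries 13 to 67 and 39 to 103. Without it Mup15 moved from -5.45 to -2.64 (adjusted p = 0.05) and Mup17 from -4.54 to -1.96 (adjusted p = 0.0406). Neither passed without deficient 3 (adjusted p = 0.0575 and 0.0567), with voom (adjusted p = 0.215 and 0.203), with robust empirical Bayes (adjusted p = 0.0635 and 0.0672) or in the limma test on FPKM (adjusted p = 0.0951 and 0.0725), and DESeq2 gave neither an adjusted p. Lrfn4 moved from -2.99 to -1.82 without wild type 1 (adjusted p = 0.0503), and did not pass without deficient 3 (adjusted p = 0.054) or with voom (adjusted p = 0.0567). H3c6, with 0 to 6 reads per deficient library, did not pass without deficient 1, 2 or 3 (adjusted p = 0.064, 0.0502 and 0.076), without wild type 1, 3 or 4 (adjusted p = 0.0704, 0.0642 and 0.0516) or with the replicate block (adjusted p = 0.0583), though its fold in these stayed between -2.28 and -2.87. In the limma test on FPKM, estimates that moved most but still passed were Ifi208 at -1.04, H4c17 at -2.72, H1f3 at -1.35, H3c1 at -1.54, H3c6 at -0.79, Mup2 at -1.20 and Mup16 at -1.19.

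**Figure D2:**
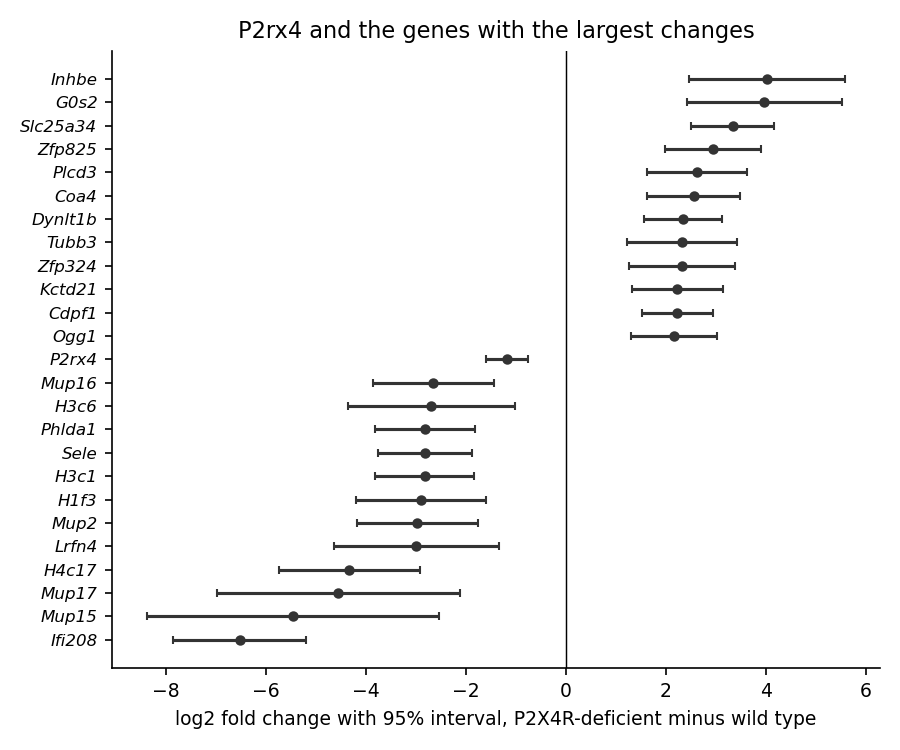
Fitted log2 fold change of P2rx4 and of the 12 largest rises and 12 largest falls, deficient minus wild type, on the horizontal axis, with 95% intervals (bars). Estimates run from -6.52 for Ifi208 to 4.03 for Inhbe.

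The number of genes past the threshold depended on particular libraries. It was 982 without wild type 3, 1224 without deficient 3 and 1482 without deficient 1. The share of higher genes was 46.6% with TMM scaling, 67.2% (1731 higher, 843 lower) when libraries were scaled by size alone and 66.3% (1602 higher, 813 lower) in the limma test on FPKM. These alternatives moved the median of all genes up by 0.145 and 0.123 on the log2 scale. Changes below are relative to the TMM scale.

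Target genes of NF-kB, the transcription factor that drives inflammatory gene expression downstream of TNF, were lower in deficient livers. Of 24 members tested, 14 fell and 0 rose (20 and 0 adjusted over the list alone), and the median log2 fold change was -1.10. Tnfaip3 (ENSMUSG00000019850), a feedback inhibitor of NF-kB, fell by 1.83 (SE 0.27), from 592 ± 129 to 166 ± 59.1 CPM (SD, n = 4, edgeR adjusted p = 0.00419). Nfkbia (ENSMUSG00000021025), which encodes the NF-kB inhibitor alpha, fell by 1.70 (SE 0.27) and Birc3, an apoptosis inhibitor, by 1.29 (SE 0.22). Sele, named above, belongs to this list, as does Il1a, an alarmin cytokine, which fell by 2.28 (SE 0.48), and by 1.64 without wild type 1. Of 20 chemokine genes, 10 fell and 1 rose, with the same counts adjusted over the list alone. The monocyte attractant Ccl2 (ENSMUSG00000035385) fell by 1.30 (SE 0.21), from 169 ± 11.6 to 68.5 ± 21.9 CPM (SD, n = 4), Ccl7 by 1.68 (SE 0.28), Ccl4 by 1.86 (SE 0.36) and the neutrophil attractant Cxcl3 by 2.02 (SE 0.41). The gene that rose was Cxcl14, at 1.22 (SE 0.30), chosen after its value was seen. Without deficient 3 the number of NF-kB members that fell was 9, and without wild type 3 Cxcl14 did not pass. In camera both lists were lower (adjusted p = 8.47e-10 for NF-kB and adjusted p = 0.000355 for chemokines), with adjusted p = 0.657 for each with an estimated correlation.

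Neutrophil markers were higher on average, while few passed singly and not every wild-type library was low. Of 15 tested, 3 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.70 on the log2 scale. The neutrophil collagenase gene Mmp8 (ENSMUSG00000005800) rose by 2.12 (SE 0.55), from 0.848 ± 0.453 to 3.71 ± 2.99 CPM (SD, n = 4). Cxcr2, a receptor for neutrophil attractants, rose by 1.53 (SE 0.44). Lcn2, which hepatocytes also express in the acute phase response, rose by 0.60 (SE 0.18), from 4922 ± 1050 to 7457 ± 450 CPM (SD, n = 4). The number that rose was 0 without deficient 4, 1 without deficient 1 or wild type 3, 6 without wild type 2 and 7 without wild type 1. Lcn2 did not pass without deficient 1, 3 or 4 or wild type 3 or 4 (adjusted p = 0.064, 0.0821, 0.0714, 0.0924 and 0.0519) or after removal of the GC trend (adjusted p = 0.0687, with a similar rise of 0.54), and Cxcr2 not without deficient 1 or 4 or wild type 2, 3 or 4 (adjusted p = 0.0691, 0.0944, 0.067, 0.0795 and 0.0702) or with the replicate block (adjusted p = 0.0512). Mmp8 did not pass without deficient 4 or wild type 3 (adjusted p = 0.063 and 0.0654), where its rise was 1.37 and 1.95. The list was higher in camera (adjusted p = 0.00241, and adjusted p = 0.66 with an estimated correlation). Deficient 4 had the highest list mean, at 3.59 log2 CPM against 2.82 to 2.90 in the other deficient libraries. Wild type 1 and 2 were near those, at 2.84 and 2.63, and only wild type 3 and 4 were low, at 1.48 and 1.49 (exact permutation p = 0.0571 for the list mean).

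Among Kupffer cell markers, genes of the resident liver macrophage, 3 of 11 fell and 0 rose, with the same counts adjusted over the list alone and a median of -0.81. These were Cd5l at -1.34 (SE 0.36), Adgre1 at -1.24 (SE 0.38) and Clec4f at -1.03 (SE 0.33). Wild type 1 carried part of these folds, and without it they were -0.74, -0.98 and -0.60. The count was 0 without deficient 1 or deficient 3, 1 without deficient 2, deficient 4, wild type 1 or wild type 2, 0 in the limma test on FPKM and with voom, and 1 with library size alone or with the replicate block. The list did not pass in camera (adjusted p = 0.0636). It did in 6 alternatives, which were FPKM with a pseudocount of 0.1 (adjusted p = 0.0432), no expression filter (adjusted p = 0.0215), library size alone (adjusted p = 0.0397), DESeq2 (adjusted p = 0.043), the replicate block (adjusted p = 0.0436) and removal of the length trend (adjusted p = 0.0392), and without wild type 3 (adjusted p = 0.0251) or wild type 4 (adjusted p = 0.00464).

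**Figure D3:**
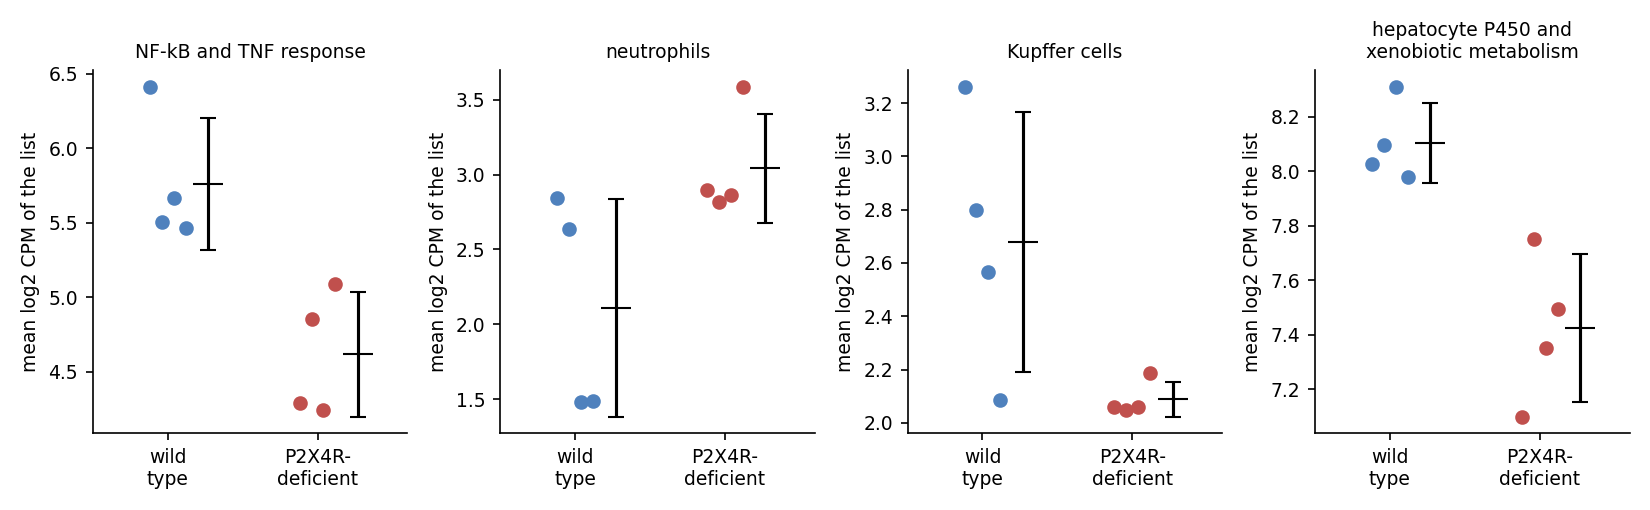
Mean log2 CPM of the tested members of 4 gene lists on the vertical axes, 1 panel per list, for each library (points) by genotype, with the group mean and SD (bars, n = 4). Means were 4.62 in deficient and 5.76 in wild-type livers for NF-kB, 3.04 and 2.11 for neutrophils, 2.09 and 2.68 for Kupffer cells, and 7.42 and 8.10 for P450 and xenobiotic metabolism.

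Interferon gamma response genes moved both ways. Of 25 tested, 5 rose and 8 fell (5 and 9 adjusted over the list alone). Igtp and Tgtp2, which encode interferon-inducible GTPases, rose by 1.08 (SE 0.18) and 1.16 (SE 0.19). Gbp7, which encodes a guanylate-binding protein, fell by 1.18 (SE 0.16), from 213 ± 22.9 to 94.1 ± 13.9 CPM (SD, n = 4). The number that fell was 1 without deficient 3, 2 without wild type 3, 4 without deficient 1 or wild type 4, and 5 without wild type 1, and the number that rose was 3 without deficient 3 or deficient 4. The list did not pass in camera (adjusted p = 0.304). Ifng itself was at 0.834 ± 0.319 CPM in deficient and 1.76 ± 0.727 CPM in wild-type livers (SD, n = 4, edgeR adjusted p = 0.0944). Of 21 type I interferon response genes, 1 fell, Oasl1 at -1.31 (SE 0.34), and the list did not pass (adjusted p = 0.067). Oasl1 also belongs to the list of genes near P2rx4, described below. Oasl1 did not pass without deficient 3 (adjusted p = 0.0629) or wild type 3 (adjusted p = 0.0596), and the number that fell was 2 without deficient 2 and 6 without deficient 4. Of 9 lymphocyte cytokine genes 2 fell, Tnfsf10 at -1.15 (SE 0.30) and Csf1 at -0.75 (SE 0.24), and the list did not pass (adjusted p = 0.111). That count was 0 without deficient 1, deficient 3 or wild type 3, and 1 without deficient 2 or wild type 2. Csf1 also did not pass in the limma test on FPKM (adjusted p = 0.105), with library size alone (adjusted p = 0.0968), with voom (adjusted p = 0.117), with the replicate block (adjusted p = 0.0698) or without wild type 1 (adjusted p = 0.11).

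The acute phase list, which holds genes of proteins that the liver makes in inflammation and genes of cytokine signalling, also moved both ways. Of 28 tested, 3 rose and 3 fell (7 and 3 adjusted over the list alone; adjusted p = 0.428 in camera). At an unadjusted p under 0.05 in edgeR, 8 were higher and 5 lower. Orm2 rose by 0.87 (SE 0.17), whereas Crp fell by 1.01 (SE 0.22) and Socs3, a feedback inhibitor of cytokine signalling, by 1.55 (SE 0.25). The remaining fall was in the cytokine gene Il6, so Crp was the only gene of an acute phase protein among the falls. Il6 did not pass without deficient 3 (-1.905, adjusted p = 0.051) or with voom (-1.457, adjusted p = 0.128). The serum amyloid gene Saa1 did not pass, with 8401 ± 2450 CPM in deficient and 5792 ± 1390 CPM in wild-type livers (SD, n = 4, edgeR adjusted p = 0.126). The number that rose was 10 with library size alone or in the limma test on FPKM, 5 without deficient 2, and 1 without deficient 3, deficient 4, wild type 3 or wild type 4. Among 14 inflammasome genes 2 fell, Il1a and Txnip, the latter by 1.84 (SE 0.29), and the list did not pass (adjusted p = 0.111).

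Of 15 monocyte and recruited macrophage genes 2 rose and 2 fell (adjusted p = 0.732). The rises were 0 without deficient 1, deficient 4, wild type 1, wild type 3 or wild type 4 and 1 without deficient 3. The falls were 0 without deficient 2, deficient 3, wild type 1 or wild type 2, with library size alone or in the limma test on FPKM, and 1 without deficient 4. The genes that fell, Mrc1 and Csf1r, also did not pass with voom (adjusted p = 0.0857 and 0.0776). Of 11 T cell and NK cell genes 1 fell, Gzma at -0.84 (SE 0.26), and 0 fell adjusted over the list alone (adjusted p = 0.936). With a library left out, Gzma passed only without deficient 4 or wild type 3, and it did not pass in the limma test on FPKM (adjusted p = 0.0685), with no expression filter (adjusted p = 0.0539), with library size alone (adjusted p = 0.0889), with voom (adjusted p = 0.0515), with the replicate block (adjusted p = 0.0576) or after removal of the GC trend (adjusted p = 0.0593). That list had a median of -0.04 and a mean of 0.02, and its median was 0.09 with library size alone. Of 12 dendritic cell and antigen presentation genes 1 fell, Zbtb46, and not without deficient 1, 3 or 4 or wild type 2 or 3 (list adjusted p = 0.936). Of 16 endothelial genes 1 rose and 2 fell (adjusted p = 0.26), and the median of -0.55 was 0.13 in the limma test on FPKM. The rise was lost without deficient 1, deficient 3, wild type 3 or wild type 4, with 2 rises without wild type 1, and 1 gene fell without wild type 1, 2 or 3.

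Of 21 stellate cell and matrix genes 5 fell, with Thbs1 at -2.20 (SE 0.35), the collagenase gene Mmp13 at -2.06 (SE 0.35) and Reln at -0.99 (SE 0.15), and the list did not pass (adjusted p = 0.0682). The number that fell was 9 without deficient 1 and 3 without deficient 3, deficient 4, wild type 2 or wild type 3, and the median of -0.12 was 0.03 with library size alone. Of 9 cholangiocyte genes 2 fell (adjusted p = 0.132), 0 without deficient 3, deficient 4 or wild type 3 and 1 without deficient 1, wild type 1 or wild type 2. Of 8 erythroid and blood genes 1 fell, Ppbp, at -1.49 (SE 0.34), and 4 fell adjusted over the list alone. All 8 were lower, with a median of -1.01, and the list did not pass (adjusted p = 0.0738). Without wild type 4, 5 fell. Only 2 B cell and plasma cell genes, 1 gene of the pancreas and other tissues and 2 genes known to differ between inbred strains (Ide at -0.25 and Wdfy1 at 0.13) could be tested, and none of them passed.

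Drug-metabolising genes of hepatocytes were lower in deficient livers. Of 26 cytochrome P450 and xenobiotic metabolism genes tested, 13 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -0.67. Cyp2a5 (ENSMUSG00000005547), a P450 of coumarin metabolism, fell by 1.44 (SE 0.26), from 465 ± 124 to 171 ± 52 CPM (SD, n = 4, edgeR adjusted p = 0.00665). Cyp3a25 (ENSMUSG00000029630) fell by 1.51 (SE 0.30) and Fmo5, a flavin monooxygenase, by 0.89 (SE 0.22). Without wild type 3 only 3 fell, without deficient 3 it was 6 and without deficient 1 it was 8. The list was lower in camera (adjusted p = 6.87e-06, and adjusted p = 0.657 with an estimated correlation).

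Of 23 bile acid and sterol genes tested, 6 rose and 9 fell, with the same counts adjusted over the list alone. The cholesterol synthesis genes Hmgcs1 (ENSMUSG00000093930) and Lss rose by 1.53 (SE 0.28) and 1.39 (SE 0.26), Hmgcs1 from 85.7 ± 23.4 to 248 ± 94.3 CPM (SD, n = 4). The canalicular transporter genes Abcc2 (ENSMUSG00000025194) and Abcb4 fell by 1.43 (SE 0.26) and 1.15 (SE 0.22). The list as a whole did not pass (adjusted p = 0.24), and 2 rose and 5 fell without deficient 3 or without wild type 3. Of 26 fatty acid and lipid genes 8 fell and 1 rose (11 and 2 adjusted over the list alone). Acly (ENSMUSG00000020917), which supplies acetyl-CoA for lipid synthesis, fell by 1.31 (SE 0.20), the fatty acid elongase gene Elovl6 by 1.07 (SE 0.18), and the peroxisomal oxidation gene Ehhadh by 1.02 (SE 0.16). The lipogenic regulator Srebf1 fell from 129 ± 27.1 to 64.4 ± 11.9 CPM (SD, n = 4). The gene that rose, Plin2, encodes a lipid droplet coat protein and was chosen after its value was seen (0.99, SE 0.30). It did not pass without deficient 1, deficient 3, deficient 4, wild type 3 or wild type 4, or with the replicate block. The list was lower in camera (adjusted p = 0.00949, and adjusted p = 0.657 with an estimated correlation), and not without deficient 2 (adjusted p = 0.0667).

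Of 23 genes of gluconeogenesis, the urea cycle and amino acid metabolism, 7 fell and 2 rose (10 and 2 adjusted over the list alone). Hgd, of tyrosine breakdown, fell by 1.23 (SE 0.21), the liver glycogen synthase gene Gys2 by 1.47 (SE 0.26) and Igfbp1 by 0.92 (SE 0.21). G6pc, of glucose release, and Arg1, of the urea cycle, rose by 1.17 (SE 0.38) and 0.60 (SE 0.17), and were chosen after their values were seen. The number that fell was 3 without deficient 1 or wild type 3, and 4 without deficient 3, wild type 2 or wild type 4, with library size alone or in the limma test on FPKM. Neither rise passed without deficient 1, deficient 4, wild type 1, wild type 3 or wild type 4 or with the replicate block (adjusted p = 0.0572 for Arg1), and G6pc not without deficient 3. The list was lower in camera (adjusted p = 0.0232, and adjusted p = 0.657 with an estimated correlation) and did not pass without deficient 3 (adjusted p = 0.0518). Of 24 genes of secreted hepatocyte proteins, 4 fell and 0 rose, with the same counts adjusted over the list alone. They included the complement gene C9 at -0.98 (SE 0.22) and Mup20 at -1.40 (SE 0.24), the latter with uncertain counts. Alb did not pass, at 67890 ± 9720 CPM in deficient and 88870 ± 5310 CPM in wild-type livers (SD, n = 4, edgeR adjusted p = 0.0884). Only 2 fell without deficient 1, deficient 3 or wild type 3, and 10 did without wild type 1. The list was lower in camera (adjusted p = 0.0016, and adjusted p = 0.657 with an estimated correlation).

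Genes whose level differs between the sexes in mouse liver were lower. Of 7 tested, 5 fell and 0 rose, with the same counts adjusted over the list alone. Cux2, a transcription factor higher in female liver, fell by 3.05 (SE 0.62), from 6.27 ± 0.558 to 0.76 ± 0.787 CPM (SD, n = 4). Cyp2b13, Cyp3a41a and Mup20 also fell, and Mup20 is higher in male liver. Cyp2b13 did not pass with the replicate block (adjusted p = 0.062), with robust empirical Bayes (adjusted p = 0.0587) or without deficient 1 or 3 or wild type 3 or 4 (adjusted p = 0.0782, 0.0732, 0.112 and 0.0566). Reads of Y-linked genes numbered 3 in deficient 1 and 0 in the other libraries. That argues against male livers in either group, and so against a difference in sex between the groups. The number that fell was 3 without deficient 1, wild type 3 or wild type 4, and in the limma test on FPKM. The list was lower in camera (adjusted p = 0.000355, and adjusted p = 0.208 with an estimated correlation).

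Purinergic signalling genes, which sense or degrade extracellular nucleotides, included P2rx4 itself. Of 17 tested, 6 fell and 0 rose (7 and 0 adjusted over the list alone), P2rx4 among them. The nucleotide-hydrolysing enzyme genes Enpp3 and Entpd8 fell by 1.40 (SE 0.28) and 1.46 (SE 0.32). Entpd8 in deficient 1 was at 2.25 log2 CPM, against 3.80 to 3.96 in the other deficient libraries. Only 3 fell without deficient 1, without wild type 4 or with library size alone. The list was lower in camera (adjusted p = 0.00411, and adjusted p = 0.605 with an estimated correlation). It was not tested without P2rx4, the targeted gene. Of 35 genes lying near P2rx4, 7 rose and 5 fell, with the same counts adjusted over the list alone. That is a larger share than the 19.9% of all genes tested. The list did not pass in camera (adjusted p = 0.304), which asks for a common direction. It passed in fry's mixed test (adjusted p = 0.000431), as did 28 of the 33 lists. Mlec and Srsf9 rose by 1.26 (SE 0.19) and 1.15 (SE 0.17), and Clip1 fell by 0.96 (SE 0.21). These counts dropped to 3 rises and 1 fall without wild type 3 and to 4 rises and 2 falls without deficient 3, and to 4 rises without wild type 2. The number of falls was 3 without deficient 1, deficient 2, wild type 1 or wild type 4, and with library size alone.

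Stress, death and housekeeping lists did not pass in camera, which asks for a common direction. In fry's mixed test, all of them but oxidative phosphorylation and ribosomal proteins passed. Adjusted p-values there were 0.000842 to 0.0151, and 0.139 and 0.544 for those that did not pass. Of 23 cell death genes 7 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.111). The growth arrest gene Gadd45a fell by 2.12 (SE 0.48), and the apoptosis effector gene Bax rose by 0.89 (SE 0.20). The number that fell was 3 without deficient 1 or deficient 3, 2 without wild type 3 and 4 without wild type 4. Of 18 ER and integrated stress genes 3 rose and 3 fell (4 and 4 adjusted over the list alone; adjusted p = 0.452), with the ER chaperone partner Sdf2l1 at 1.38 (SE 0.27), and 1 fell without deficient 1, deficient 3, wild type 2 or wild type 3. Of 14 oxidative stress genes 2 fell, Osgin1 at -2.29 (SE 0.39) and Hmox1, of heme breakdown, at -1.45 (SE 0.31; list adjusted p = 0.21). Of 12 heat shock genes 3 fell (4 adjusted over the list alone, camera adjusted p = 0.0553), with the chaperone gene Hsph1 at -1.42 (SE 0.20), and 1 fell without deficient 3, wild type 3 or wild type 4. The others that fell, Bag3 and Hspa8, did not pass with library size alone (adjusted p = 0.055 and 0.0878) or in the limma test on FPKM (adjusted p = 0.055 and 0.081). With the replicate block they did not pass either (adjusted p = 0.068 and 0.0845). Of 20 circadian clock genes 2 rose and 4 fell (adjusted p = 0.67), with Tef at 0.98 (SE 0.15) and Nfil3 at -0.90 (SE 0.21). There 1 fell without deficient 3 or wild type 3, 2 without deficient 1, deficient 4 or wild type 4, and 1 rose without deficient 4 or wild type 3. Of 20 hypoxia and glycolysis genes 4 rose and 3 fell (adjusted p = 0.995), with 1 rise without wild type 2 or 3, 2 without deficient 3, deficient 4 or wild type 1, 1 fall without deficient 3 or wild type 3, and 5 falls without deficient 2. Of 21 oxidative phosphorylation genes 1 fell, and 0 adjusted over the list alone (adjusted p = 0.29) or without deficient 1, 3 or 4 or wild type 3 or 4. None of 18 cell cycle genes passed in edgeR, with 2 higher at an unadjusted p under 0.05 and 2 rises without wild type 1 (adjusted p = 0.429 for the list in camera), and none of 20 ribosomal protein genes, with 0 at that level (adjusted p = 0.781). Medians of the clock, hypoxia and ribosomal lists were -0.08, -0.05 and -0.03, and 0.06, 0.09 and 0.11 with library size alone.

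In all, camera called 9 of 33 lists, 1 higher and 8 lower. None of the 9 held with an estimated correlation in camera, where 2 lists had an unadjusted p under 0.05, and 6 lists passed in fry's directional and 28 in its mixed test. Exact two-sided permutation tests of list means over the libraries gave p = 0.0286, the smallest possible, for 10 lists, and an adjusted p of 0.103 at best. With that smallest p and 36 list means, an adjusted p under 0.05 would have needed many more lists at it, so these adjusted values decide little.

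**Figure D4:**
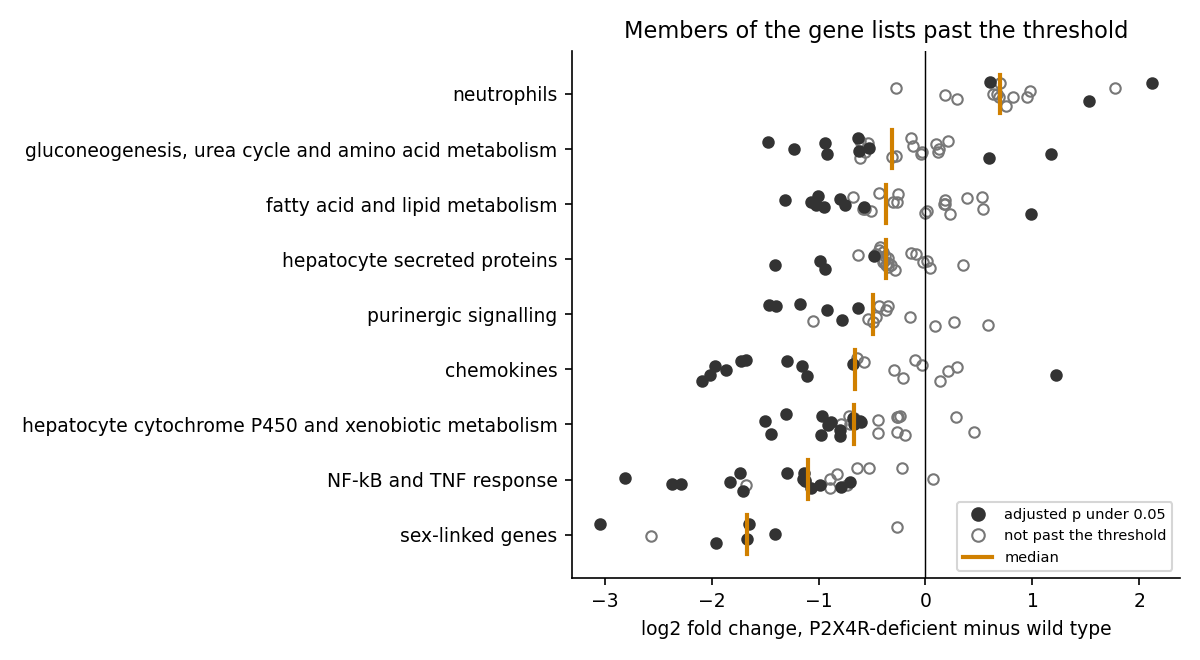
Fitted log2 fold change, deficient minus wild type, on the horizontal axis for each tested member (points) of the 9 gene lists called by camera, which are placed along the vertical axis, with list medians (bars). Filled points passed the edgeR threshold. Medians run from -1.67 for sex-linked genes to 0.70 for neutrophils.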

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

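The tests of a mislabelled library, of a donor-strain segment and of a general loss of hepatocyte RNA were chosen only after the result was seen. Predictions for splits, GC content, Kupffer cells and short-lived transcripts were written before those tests were run, and removal of the GC trend was itself added after the data were seen. For each named gene, list mean and library measure, the gap between the most distant library of a group and its nearest neighbour was divided by the range of the group. A large value marks a library far from the other 3, and 22 of 404 groups passed, against 20.2 expected by chance.

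Deficient 1 lay apart for 7 of these. They were H3c1 (0.877), Entpd8 (0.909), Cxcl3 (0.88), Ern1 (0.928), the bile acid and sterol list (0.89, at 5.33 log2 CPM against 5.80 to 5.86), the oxidative phosphorylation list (0.839) and the number of genes with reads (0.931, 14414 against 14023 to 14050). Wild type 1 lay apart for 6, which were H3c6 (0.959), Il1a (0.84, at 3.48 log2 CPM against 1.59 to 1.89), Igfbp1 (0.893), Serpinc1 (0.935), Arntl (0.897) and the P2rx4 neighbourhood list (0.902). Deficient 3 did for Vps33a (0.877), Mcm2 (0.942) and the ER stress list (0.857), and deficient 4 for the neutrophil list (0.9) and the Kupffer list (0.905, at 2.19 log2 CPM against 2.05 to 2.06). Deficient 2 did for Bax (0.921), wild type 2 for Krt19 (0.907, at 3.55 log2 CPM against 0.43 to 0.72) and Chac1 (0.863), and wild type 3 for Zfp825 (0.894).

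Chance division of the libraries is argued against for the number of genes past the threshold, without being excluded. The genotypes gave 2264 genes and the highest other split gave 1, so that 1 of 35 splits had as many. That is the smallest share these splits can give. Every other split also mixes the genotypes, which widens the spread within its groups and lowers its number of calls. Chance division is not argued against for the number of gene lists called by camera. There the genotypes gave 9, the highest other split gave 16, and 18 of 35 splits had as many.

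P2rx4 was lower in every deficient liver and was still read in each. The highest deficient level was 0.677 times the lowest wild-type level, which restates that pattern and is no separate test of a mislabelled library. A segment of donor-strain DNA around the gene would raise the share of changed genes nearby. That share was 25.4% of 169 genes within 10 Mb, against a median of 20.1% and a 95th percentile of 26% in 10000 runs of neighbouring genes elsewhere. A segment and its absence thus cannot be told apart. The fixed list of 35 genes near P2rx4, with 7 rises and 5 falls, was not set against such runs. An altered P2rx4 transcript in the deficient genotype stays open.

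P450 genes were lower. GC content is argued against, since 13 of 13 were still lower after the GC trend of each library was removed. A loss of hepatocyte RNA that raised other cell types alike was examined with neutrophil minus Kupffer list means. These differed by 1.52 log2 units (0.95 ± 0.30 in deficient, -0.57 ± 0.39 in wild type, SD, n = 4, exact permutation p = 0.0286), so these lists did not move alike. That restates the higher neutrophil and lower Kupffer list means already seen and is no separate test. A change in neutrophils alone would do the same, so the loss is not decided by it. An earlier test of that loss, P450 minus secreted-protein list means, gave -0.29 (exact permutation p = 0.0857) and did not decide. Without the Mup genes, whose counts are uncertain, it gave -0.34 (exact permutation p = 0.0571). An effect of genotype on these genes stays open.

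NF-kB target genes were lower while neutrophil markers were higher. GC content is argued against for the target genes, since 14 of 14 were still lower without the GC trend, and the median of the neutrophil markers was 0.73, from 0.70. A lower share of Kupffer cells and its absence cannot be told apart, as NF-kB minus Kupffer list means differed by -0.55 log2 units (exact permutation p = 0.0857). A general fall of short-lived induced transcripts is not argued against, since immediate-early genes not looked at before had a median log2 fold change of -0.82 and were lower in camera (adjusted p = 3.27e-07), though not with an estimated correlation (adjusted p = 0.429). A difference in NF-kB activity between the genotypes and a difference in the timing of the response both stay open.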

How the results depend on the processing

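P2rx4 was lower and past the threshold under every alternative, with log2 fold changes of -0.87 to -1.29, and no gene past the threshold changed sign under any. Of 161 named genes 119 passed, and 78 of these kept direction and side of the threshold in every other and left-out setting in which they were tested. Genes past the threshold numbered 2264 at first, 2174 to 2945 under other filters, scalings and tests, 1768 with the replicate block, and 982 (without wild type 3) to 2388 (without deficient 2) with a library left out, where fewer libraries were tested. Higher genes numbered 1055, against 1731 with library size alone, 1602 in the limma test on FPKM, 1594 with its pseudocount of 0.1, 1368 with DESeq2, and 454 (without wild type 3) to 1079 (without deficient 2) with a library left out. Lower genes numbered 1209, against 843 with library size alone, 813 and 814 in the tests on FPKM, 1577 with DESeq2, and 528 (without wild type 3) to 1309 (without deficient 2) with a library left out. Library size alone differs from the edgeR test used here only in leaving out the TMM factors. These were 1.008 to 1.077 in deficient and 0.918 to 1.001 in wild-type libraries. FPKM values leave them out too, with other changes of test and filter. The cause of the other differences was not tested. Camera called 9 lists, 14 with library size alone, 0 with an estimated correlation, and 8 (without deficient 3) to 18 (without wild type 4); the cause was not tested. Lists short of the threshold that passed in some settings were type I interferon, lymphocyte cytokines, inflammasome, cell death, Kupffer, endothelial, stellate, cholangiocyte, heat shock and erythroid genes.

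Direction reversed for 2 named genes, neither past the threshold. Cd79b was at -0.19, and at 0.009 in the limma test on FPKM, 0.077 with its pseudocount of 0.1, 0.564 with voom, 0.09 with the replicate block, and -0.589 (without deficient 4) to 0.783 (without wild type 1); the cause was not tested. Krt19 was at -1.15, and at -1.766 (without deficient 1) to 0.349 (without wild type 2), since wild type 2 held 165 of its wild-type reads and the others 19 to 24.

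The replicate block left P2rx4 at -1.19. It ended the calls of the named genes Adgre1, Adora2a, Arg1, Bag3, Chil3, Clec4f, Csf1, Cxcr2, Cyp2b13, Gzma, H3c6, Hspa8, Pkhd1, Serpinc1 and Uqcrc2, with folds about as large as before (Clec4f moved most, from -1.03 to -0.89), and Ddx58 gained a call (-0.80, adjusted p = 0.0452). Correlations of same-numbered libraries after removal of group means were 0.13, -0.11, 0.07 and -0.11, and no library correlated best with its own number. The mitochondrial share was 10.52% in deficient 1 and 10.13% in wild type 1, and 3.81% to 6.66% in the other libraries, so a factor shared by these 2 is not excluded. FPKM quantile normalisation, FPKM rescaling and array weights were not run, as they apply to an FPKM test that the counts replaced, and DESeq2 size factors, library size alone and voom with quality weights took their place. Removal of the GC trend (2313 genes) and of the length trend (2344) was added after the data were seen. In simulated counts 49% of 2-fold changes were recovered, so genes short of the threshold at this depth and n = 4 may still differ. The simulation changed a smaller share of genes than the 19.9% called here, so its recovery rate may not carry over.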

Other observations

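The gene lists in this part, the genes named from them and the histone test were chosen after the values were seen, while the zinc finger test was written before it was run. Immediate-early genes, transcription factors and regulators induced within an hour of a stimulus, were lower in deficient livers. Of 27 tested, 12 fell and 0 rose, with a median log2 fold change of -0.86 (camera adjusted p = 1.75e-09, and adjusted p = 0.429 with an estimated correlation). Myc fell by 1.80 (SE 0.34), from 152 ± 20.3 to 43.4 ± 27.2 CPM (SD, n = 4), Ier2 by 1.77 (SE 0.31), Egr1 by 1.93 (SE 0.44) and Jun by 1.73 (SE 0.42). Only 8 fell without deficient 3 or wild type 3, and 17 did with DESeq2.

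Of 20 cholesterol synthesis genes 9 rose and 0 fell (median 0.63; adjusted p = 0.473 with an estimated correlation), with Msmo1 at 1.37 (SE 0.21), from 59.4 ± 14.4 to 153 ± 29.8 CPM (SD, n = 4). Of 22 genes of bile acid synthesis and transport 12 fell and 0 rose (median -0.87; adjusted p = 0.429 with an estimated correlation), with the bile acid reductase gene Akr1d1 at -1.97 (SE 0.38) and the bile acid uptake gene Slc10a1 at -1.46 (SE 0.30). Cyp7a1, of the first step from cholesterol to bile acids, fell by 3.13 (SE 0.62) at a low level, from 1.23 ± 0.459 to 0.136 ± 0.106 CPM (SD, n = 4). These counts were 4 rises and 6 falls without deficient 3 or without wild type 3. Of the KEGG pathways, set without regard to these values, terpenoid backbone biosynthesis had 9 of 22 genes that rose and 2 that fell (median 0.30, camera adjusted p = 0.0768) and steroid biosynthesis 4 of 17 that rose and 2 that fell (median 0.11, camera adjusted p = 0.464), and neither passed. Primary bile acid biosynthesis had 6 of 16 that fell and 0 that rose (median -0.64, camera adjusted p = 0.00355, and adjusted p = 0.611 with an estimated correlation).

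Of 19 genes higher in female than in male mouse liver, 11 fell and 0 rose (median -1.44; adjusted p = 0.376 with an estimated correlation). Cyp2a4 (ENSMUSG00000074254) fell by 2.02 (SE 0.18), from 489 ± 77.8 to 121 ± 19.1 CPM (SD, n = 4), and Abcd2 by 2.34 (SE 0.51). The number that fell was 6 without wild type 3 or wild type 4 and 7 in the limma test on FPKM. Of 14 major urinary protein genes, which are higher in male liver, 10 fell and 0 rose (median -2.50, adjusted p = 0.429 with an estimated correlation). Near-identical copies make their counts uncertain, and 4 fell without deficient 3 and 6 without wild type 3. In the limma test on FPKM 4 fell (median -1.19), and 5 did with voom or with robust empirical Bayes. The genes of the 3 C1q chains, which Kupffer cells express, had a median of -0.78 and none passed, with 1 lower at an unadjusted p under 0.05. Their median was -0.22 without wild type 1, -0.37 with voom and -0.41 in the limma test on FPKM.

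Of 19 replication-dependent histone genes 7 fell and 0 rose (median -1.41; adjusted p = 0.429 with an estimated correlation), and 4 fell without deficient 3 or without wild type 3. A lower share of dividing cells would have lowered the cell cycle list as well, and its median was 0.27, with 12 members higher and 6 lower and none past the threshold. The proliferation marker Mki67 was lower at -0.82 (SE 0.41, adjusted p = 0.179). With 18 of 25 listed genes tested and members on both sides, the list does not decide that explanation. Most histone transcripts lack a poly-A tail, and libraries were made from polyadenylated RNA, so these counts may depend on how much RNA without a tail was carried along. That was not tested.

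Of 249 genes with symbols of the Zfp series, most of them zinc finger transcription factors, 47 rose and 8 fell (median 0.44; adjusted p = 0.376 with an estimated correlation), and 79.5% were higher. Low expression is argued against, since the central 95% of the medians of 10000 random lists matched for expression ran from -0.01 to 0.19. The series is set by symbol and includes unrelated genes such as Zfp36, an mRNA decay factor, which fell by 1.73 (SE 0.40). The number that rose was 14 without wild type 3, 17 without deficient 3, 26 without deficient 1 or deficient 4, 27 with the replicate block and 73 with library size alone.

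The adjusted p-values of the lists above were adjusted together with the fixed lists, over 41 in all, and since the lists were chosen after their values were seen, they describe these genes and test nothing new. Of 338 KEGG pathways annotated in the deposited table and adjusted over themselves, 66 were lower and 5 higher in camera, and 0 with an estimated correlation, where 24 had an unadjusted p under 0.05. Retinol metabolism was the first of those lower, with 30 of 68 genes that fell and 2 that rose (adjusted p = 1.31e-09, and adjusted p = 0.611 with an estimated correlation). TNF signaling was lower, with 33 of 98 that fell and 3 that rose (adjusted p = 0.000248, and adjusted p = 0.611 with an estimated correlation). Basal transcription factors were higher, with 8 of 38 that rose and 2 that fell (adjusted p = 0.0196, and adjusted p = 0.611 with an estimated correlation).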
